A study of Mus musculus with 6 samples.

How the data were processed

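The data were 6 RNA-seq libraries of lung endothelial cells from mice at postnatal day 7, per the labels. The cells were purified by fluorescence-activated sorting. Per the labels' protocols, between 100 and 200 ng of total RNA per sample went into poly(A) selection and library preparation with New England BioLabs kits, and paired reads of 76 nt were aligned to the mouse genome mm10. Per the submitters' processing notes, the tools were TopHat2 2.0.14, Bowtie2 2.2.3, Cufflinks 2.2.1 and Cuffdiff. Whether counting used the strand is not given in the sources used here, so overlapping genes cannot be told apart with certainty. Replicates are separate samples of a group in the labels, which do not say that each came from its own animal, so the p-values measure the spread between these samples.

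The authors deposited 1 table of FPKM values per library, with a gene symbol for each row, and beside them a log2 fold change and a p-value. FPKM divides by transcript length and by the library's fragments, and short RNAs can reach very high values: Mir5133 was listed at 99452 FPKM in control A and at 0 elsewhere, which made short RNAs 20.2% of that library's FPKM sum, against 0.689% to 3.96% in the others. A share of the FPKM sum is not a share of the fragments. Recomputation showed that the authors' deposited log2 fold change is the mean of the log2 ratios within the 3 letter pairs and that the deposited p-value is a paired test over these pairs without adjustment, with a largest difference from the recomputed p of 8.11e-13. Rows with a 0 in any library hold spreadsheet errors there.

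FPKM holds no counts, so no count model was used. Relative depth was read from rows with values above 0 and under 0.1 FPKM in both of 2 libraries, where the commonest ratio is that of what 1 fragment is worth. Between 724 and 870 rows served for each library against control A, of which 215 to 322 lay within 0.02 (log2) of the commonest ratio. Ratios taken directly and through control A differed by at most 0.00075 (log2).

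The table held 23793 rows, of which 5974 were 0 throughout, 333 joined several symbols with commas, 256 repeated a symbol and 26 had a number in place of the symbol, as left by a spreadsheet. Levels were compared on the log2(FPKM + 1) scale with limma 3.58.1 in R 4.3.3, with an empirical Bayes trend and Benjamini-Hochberg adjustment over the 11693 rows with a mean of at least 1 FPKM. Fold changes are on that scale and understate the change of low genes. Errors are the SD over 3 libraries for levels and the SE for fold changes. The threshold was an adjusted p of 0.05. Gene positions come from RefSeq on GRCm38, which is the same build as mm10; 11643 of the tested rows matched by symbol or synonym and 50 did not.

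Before the data were examined, 28 gene lists with 350 entries, the tests, the alternatives and the rule for named genes were fixed. The lists covered markers of Car4-high capillary, general capillary, arterial, venous, lymphatic and pan-endothelial cells; VEGF receptors, tip cell, growth factor early response, Notch, Wnt, BMP and TGF-beta, S phase, G2 and M phase, hypoxia, interferon, inflammation, MHC class II, p53, dissociation stress, basement membrane, and caveola and lipid uptake genes; and markers of alveolar type 1, alveolar type 2 and airway, leukocyte, mesenchymal, mesothelial, and erythroid and platelet cells. They were written from general knowledge of lung endothelium, which may include genes first described with these samples, so the marker lists are not independent evidence. Lists were tested with camera at a preset correlation of 0.01. The rule for named genes took called genes whose groups do not overlap, up to 12 in each direction by size of change, without predicted genes, clone names or ribosomal pseudogenes; Vegfa, Flt1, Kdr, Car4 and Plvap; and up to 4 genes of lowest p in each list.

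The letters A, B and C were checked for pairing. Deviations from the group means correlated across genes between libraries with the same letter, at 0.36 for A, 0.27 for B and 0.19 for C, all above the threshold of 0.1 set in advance, and every library correlated best with its own letter. Without the sex chromosomes the values were 0.35, 0.25 and 0.15. The pairing comes from the letters in the sample titles and from these correlations. The description label has another prefix for pair A than for pairs B and C, with no stated meaning. The main test had no block, and results with the block are given where they change a call.

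Alternatives were other pseudocounts, filters, scalings and variance models, the block, a batch term from the label prefix, the leaving out of each library, and list tests with an estimated correlation or with fry. With an estimated correlation camera also rests on the 4 residual degrees of freedom of the fit, so a list can lose its call without gene correlation. Removing short RNA rows, removing pair B or pair C, the block together with an estimated correlation, and the level of mesenchymal markers as a covariate were added after the data were seen. The scripts were also tested on simulated data, written after the first fit of the real data: in 10 simulations of the mutant and control comparison over 11693 rows with 200 changed genes each, limma recovered 67.5% of genes changed by 1, 91.5% of those changed by 2 and 95% of those changed by 3 on the log2 scale, with decreases that reach 0 FPKM counted, with a mean of 9 false calls. In the same simulations camera called a list shifted by 1 in all 10, and 1 of 250 tests of other lists. These simulations have no correlation between genes and no pairing. They hold more changed genes than the 16 called in the real data, which loosens the adjusted threshold. The shares recovered are therefore not the power of the real comparison.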

Results

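RNA was measured by sequencing in endothelial cells, which line blood and lymph vessels, sorted from mouse lungs at postnatal day 7. There were 6 libraries, 3 from control lungs and 3 from mutant lungs, and each group held replicates A, B and C. Libraries that share a letter are called a pair below. The sample titles name Vegfa and Shh, the series title names Vegfa made by the epithelium, and the labels do not spell out the alleles, so the groups are called control and mutant here. The comparison asks which transcripts of lung endothelial cells differ between mutant and control lungs. Levels were given in FPKM (fragments scaled to transcript length and to the library's fragments) for 23793 rows, of which 11693 had a mean of at least 1 FPKM and were tested. The total number of fragments is not known. The spacing of the lowest values gave relative depths of 1.29 for control B, 0.897 for control C, 0.94 for mutant A, 1.35 for mutant B and 1.49 for mutant C, with control A as 1. Pair C came from male mice and pairs A and B from female mice by the transcripts of the sex chromosomes: Xist stood at 0.0924 FPKM in control C and 0.071 FPKM in mutant C, and between 33.3 and 57.9 FPKM in the other libraries.

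Vegfa, which encodes the ligand of the endothelial receptors Kdr and Flt1 (chromosome 17, 46016993 to 46032377, mouse build GRCm38), did not differ between the groups beyond the spread of the replicates. It stood at 80.9 ± 7.86 FPKM (SD, n = 3) in control and 81.6 ± 17.1 FPKM in mutant endothelial cells, a log2 fold change of -0.0041 ± 0.17 (SE) with an adjusted p of 0.996 in limma. Because the series title places the change of Vegfa in the epithelium and the libraries hold sorted endothelial cells, this level does not check the labels. Kdr was at 296 ± 16.5 and 243 ± 40.4 FPKM (log2 fold change -0.29 ± 0.14, adjusted p = 0.67), and Flt1 at 74.2 ± 7.87 and 69.7 ± 6.53 FPKM (-0.09 ± 0.12, adjusted p = 0.885). None of the 5 VEGF receptors and co-receptors measured passed the test. Their median log2 fold change was -0.09 and their mean 0.04, and the test of the list pointed down (camera, adjusted p = 0.614).

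The genes that passed the adjusted threshold were all lower in the mutant. Chst1, a sulfotransferase that modifies carbohydrate chains, fell from 22.8 ± 1.92 to 1.8 ± 0.552 FPKM (log2 fold change -3.10 ± 0.17, adjusted p = 0.00155). Emp2, a small membrane protein, fell from 139 ± 17 to 15.3 ± 8.06 FPKM (-3.21 ± 0.31, adjusted p = 0.0267). Sirpa, the receptor of the surface protein CD47, fell from 32.5 ± 2.73 to 4.63 ± 0.0882 FPKM (-2.57 ± 0.10, adjusted p = 0.000448), and the keratin Krt80 fell from 24.9 ± 3.09 to 3.25 ± 0.219 FPKM (-2.60 ± 0.12, adjusted p = 0.000907). Tbxa2r, the receptor of thromboxane, fell from 31 ± 2.72 to 7 ± 1.72 FPKM (-2.02 ± 0.17, adjusted p = 0.0155).

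A further 6 of the called genes named by the rule follow. The log2 fold change was -2.62 for Cdkn2b, an inhibitor of cyclin-dependent kinases, -2.74 for Begain, -1.76 for the phosphodiesterase Pde8b, -1.59 for AW112010, -1.59 for the kinesin Kif26b and -1.20 for the transporter Slc22a23. The log2(FPKM + 1) scale understates the change of genes at low levels: Begain was at 7.54 ± 1.08 FPKM in control and 0.282 ± 0.177 FPKM in mutant libraries. A further 4 called genes lay outside the naming rule and were chosen after their values were seen: the log2 fold change was -1.19 for Enho, -1.05 for the calcium channel Orai2, -1.04 for the chemokine Cx3cl1 and -0.98 for Nhlrc2. Adjusted p of these 10 genes lay between 0.00331 and 0.04. The small nucleolar RNA Snora17 was listed at 20.3, 51.6 and 50.2 FPKM in the controls and at 0 in all 3 mutants (adjusted p = 0.00331). It lies inside Snhg7 on chromosome 2, so its value is uncertain, and Sirpa belongs to a family of similar genes whose reads can be shared.

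In all, limma called 16 genes lower and 0 higher in the mutant at an adjusted p under 0.05. At an unadjusted p under 0.05 it gave 502 lower and 445 higher, against 584.6 in all expected by chance. The limma fit with the pair as a block gave 1434 genes at that unadjusted threshold, 630 of them higher in the mutant, against the same 584.6. Each of the 16 was lower in all 3 pairs, with the 3 mutant libraries below the 3 controls. With the pair as a block, 6 genes were lower and 0 higher, and these 6 (Snora17, Chst1, Begain, Krt80, Sirpa and Tbxa2r) were among the 16. The count rested on the full set of libraries: it was 6 without control A, 6 without control B, 5 without control C, 6 without mutant A, 8 without mutant B and 8 without mutant C. Among the 4 libraries of pairs B and C, whose description labels share a prefix, 5 genes were lower and 1 higher; pair A, with another prefix, holds 1 library per group and allows no test.

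**Figure D1:**
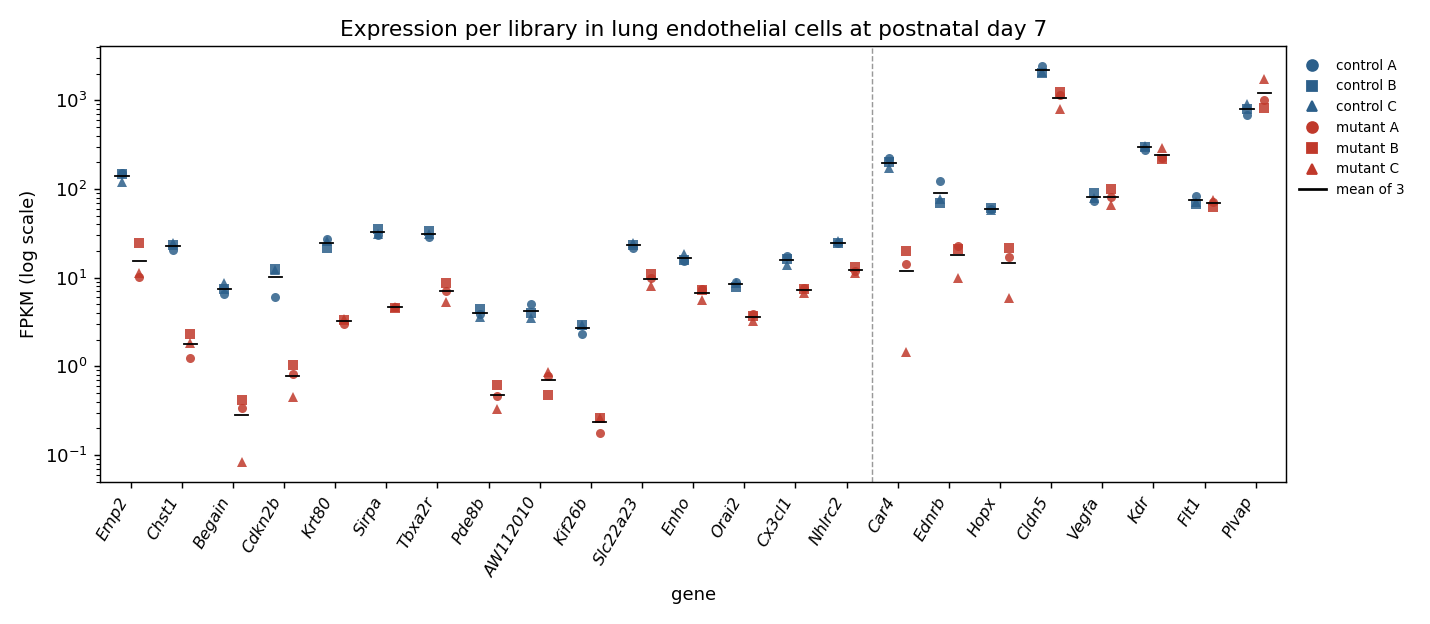
FPKM per library (log axis) for the called genes other than Snora17, left of the dashed line, and for 8 genes that did not pass, right of it; blue marks are control and red marks mutant libraries, shapes give the replicate letter and black bars the mean of 3. Sirpa lies near 32.5 FPKM in control and 4.63 FPKM in mutant libraries, Car4 varies most among the mutants, and Vegfa overlaps between the groups.

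Markers of the capillary cells that carry high Car4 (carbonic anhydrase 4) were lower in the mutant as a group. Of the 13 measured, 12 had a lower mean in the mutant, 2 (Chst1 and Emp2) passed over all genes tested, and 7 passed adjusted over the list alone. Car4 itself (chromosome 11, 84957754 to 84966054) was at 226, 201 and 170 FPKM in controls A, B and C and at 14.1, 20 and 1.43 FPKM in mutants A, B and C. Its log2 fold change of -4.44 ± 0.75 was larger in size than that of every named gene but Snora17, yet it did not pass over all genes (adjusted p = 0.21). Mutant C set that spread: without it the log2 fold change was -3.48 and the adjusted p 0.00855. Ednrb, an endothelin receptor, was at 90.4 ± 29 and 17.9 ± 6.88 FPKM (-2.31 ± 0.34, adjusted p = 0.11). Both passed adjusted over the list alone, as did Tbx2, Kitl and Fibin. The median of the list was -1.43, with medians of -1.65, -0.82 and -2.08 within pairs A, B and C. The camera test with its preset correlation gave an adjusted p of 2.88e-13, and the adjusted p was 0.0528 with an estimated correlation. The rotation test fry gave 0.0064. The list may include genes first described with these samples, so these tests are not independent evidence.

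The markers of the other capillary type did not fall with them as a set. Among 12 general capillary markers, 0 passed over all genes and 0 passed adjusted over the list alone (2 were lower with the pair as a block). Their median was 0.11, their mean -0.05 and the test pointed up (adjusted p = 0.727). The list was mixed, with 4 markers lower and 8 higher in mean in the mutant. Hilpda, Ntrk2 and Sema3c were lower in every pair (log2 fold changes -0.93, -0.60 and -0.71, limma adjusted p of 0.593, 0.617 and 0.717). Plvap, the diaphragm protein that marks general capillary cells, was at 797 ± 119 FPKM in control and 1198 ± 496 FPKM in mutant libraries (0.52 ± 0.30, adjusted p = 0.714). The 10 arterial markers had a median of 0.01 (adjusted p = 0.924). The 9 venous markers had a median of 0.01 and a mean of 0.14 while the test pointed down (adjusted p = 0.919), and with the block 1 was lower and 1 higher over the list alone. The 7 lymphatic markers had a median of 0.19 (adjusted p = 0.51, 0.019 without control A, 0.926 with an estimated correlation and all libraries). Their mean turned from 0.20 to -0.23 with the mesenchymal covariate described below (camera adjusted p = 0.0382). The 16 pan-endothelial genes had a median of 0.06 and a mean of -0.03, and the test pointed down (adjusted p = 0.727; 0.0319 with the mesenchymal covariate described below). Cldn5, a tight junction protein, passed adjusted over that list alone, at 2190 ± 210 FPKM in control and 1069 ± 239 FPKM in mutant libraries (-1.06 ± 0.22, adjusted p = 0.288 over all genes), and 2 of the list passed with the block.

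Genes of the cell cycle were higher in the mutant as a group under the preset correlation only. All 18 S phase genes had a higher mean in the mutant (median 0.59, adjusted p = 5.21e-13), and the adjusted p was 0.48 with an estimated correlation. Over all genes 0 passed, and 13 passed adjusted over the list alone, against 2 with the pair as a block. Cdt1, which licenses replication origins, was at 10.7 ± 1.85 and 20.3 ± 3.67 FPKM (0.86 ± 0.17, adjusted p = 0.262). The helicase subunits Mcm7, Mcm6 and Mcm3 had log2 fold changes of 0.64, 0.59 and 0.69. All 20 genes of G2 and M phase also had a higher mean (median 0.58, adjusted p = 1.25e-09), with an adjusted p of 0.66 with an estimated correlation, and 0 passed over all genes or over the list alone. The difference was uneven between pairs: the S phase medians were 0.08, 1.09 and 0.59 and the G2 and M medians 0.05, 1.30 and 0.25 within pairs A, B and C.

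Genes that endothelium switches on in inflammation had higher means in the mutant for all 11 measured (median 1.04, adjusted p = 1.59e-06), but the adjusted p was 0.283 with an estimated correlation. None passed over all genes, and 2 passed adjusted over the list alone, against 7 with the block. These 2 were Tnfaip3, an inhibitor of NF-kB signalling (19.1 ± 2.41 and 32.5 ± 6.34 FPKM), and the cytokine Il6 (0.911 ± 0.075 and 3.2 ± 1.3 FPKM). The adhesion molecule Sele was at 1.49, 2.3 and 1.51 FPKM in controls A, B and C and at 9.43, 3.23 and 41.3 FPKM in mutants A, B and C. The 15 dissociation stress genes had a median of 0.23 (adjusted p = 0.382), with 1.52e-05 without control B and 0.926 with an estimated correlation and all libraries. Leukocyte markers, 8 measured, had a median of -0.32 (adjusted p = 0.375). That list passed without control C (6.96e-05) and without mutant A (0.00132), and its adjusted p with an estimated correlation and all libraries was 0.926.

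The targets of p53 were slightly lower as a group, with 10 of 11 lower in mean (median -0.15, adjusted p = 0.00507). The adjusted p was 0.283 with an estimated correlation, 0.0256 with fry and 0.053 without mutant B. The pro-apoptotic gene Bbc3 (20.8 ± 1.45 and 12.8 ± 1.68 FPKM) and Phlda3 (43.3 ± 2.81 and 31.1 ± 1.21 FPKM) passed adjusted over the list alone, and 0 passed over all genes. The 17 early response genes of growth factor signalling had a median of 0.13 (adjusted p = 0.0976) and passed with the block (0.0427), where 2 were higher over the list alone. They also passed without control B (0.00803), without control C (0.0173) or without mutant A (0.000515), and with the mesenchymal covariate described below, where their mean rose from 0.26 to 0.55 (1.84e-05). The 14 basement membrane genes had a median of 0.21 (adjusted p = 0.0704), and passed with the block (0.0137), without control C (0.0127) and without mutant A (0.00564). Over that list alone Col18a1 was higher, at 23 ± 3.9 and 35.9 ± 3.04 FPKM, and with the block 4 genes were. With an estimated correlation the adjusted p of both lists was 0.926, and 0.657 with the block and an estimated correlation.

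The remaining pathway lists did not pass with all libraries and 0 of their genes passed. The medians were 0.20 for 14 tip cell genes (adjusted p = 0.375), -0.02 for 11 Notch pathway genes (0.534), -0.16 for 7 Wnt targets (0.375) and 0.07 for 10 targets of BMP and TGF-beta (0.919). They were 0.01 for 15 hypoxia response genes (0.831), -0.07 for 12 interferon response genes (0.68) and -0.33 for 4 MHC class II genes (0.484). The last 2 lists passed without control C, with adjusted p of 0.0267 and 0.00464, and both had 0.926 with an estimated correlation and all libraries. The 12 caveola and lipid uptake genes had a median of 0.05 and a mean of 0.14 while the test pointed down (0.987). In all, 9 of the 28 lists passed with the preset correlation and 0 with an estimated one, and the other groupings of the 6 libraries into 3 and 3 gave 6 to 13 lists with the preset correlation.

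**Figure D2:**
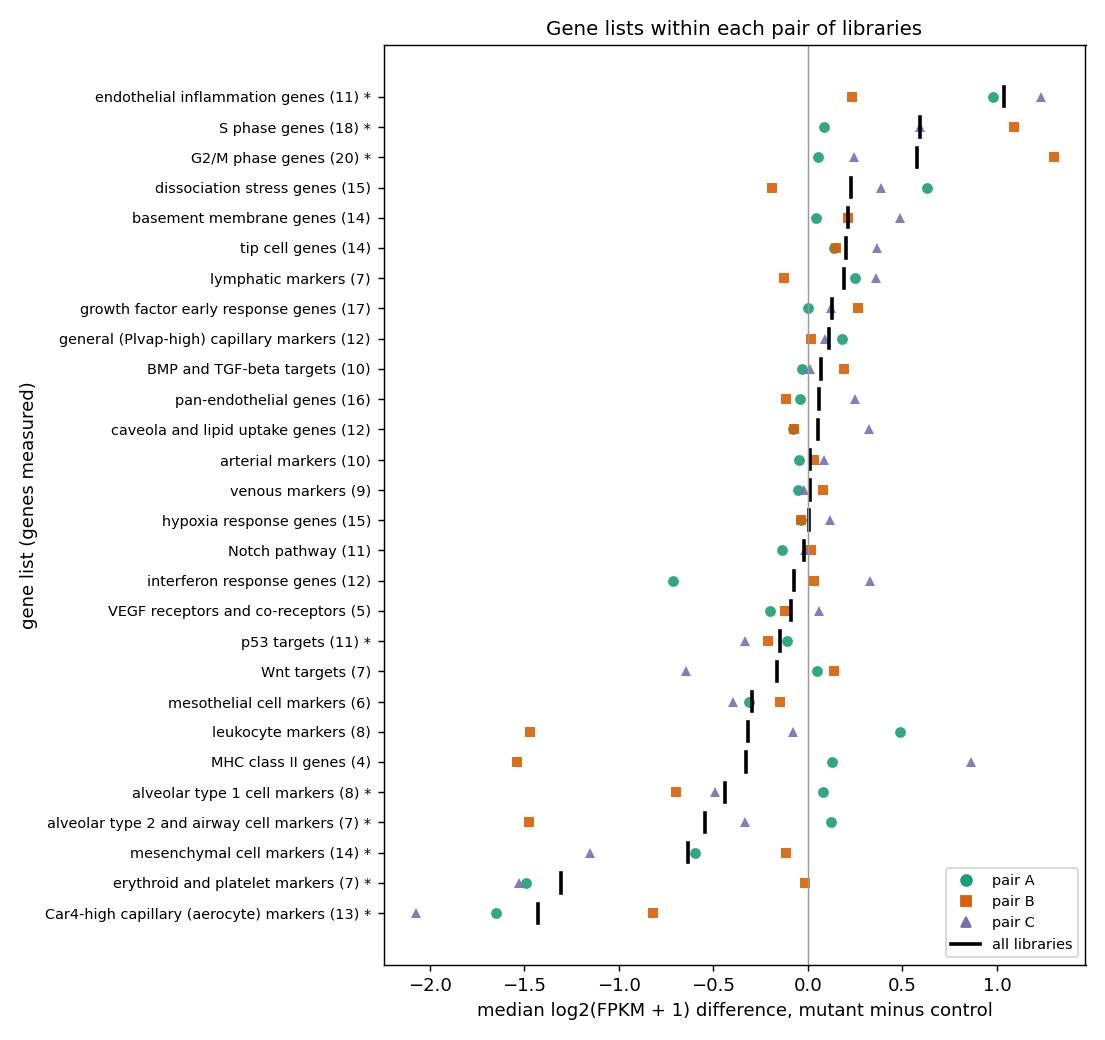
Median log2(FPKM + 1) difference between mutant and control (horizontal axis) for each of the 28 lists, with the number of genes measured in brackets; coloured marks are the 3 pairs, black bars the median over all libraries, and an asterisk marks an adjusted p under 0.05 in camera with the preset correlation. The markers of Car4-high capillary cells have the lowest median, -1.43, and pair B has the highest of the 3 medians in both cell cycle lists.

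Transcripts of other lung and blood cells also differed between the libraries, at levels that varied from pair to pair. The 7 erythroid and platelet markers were lower as a group (median -1.31, adjusted p = 1.92e-06), with an adjusted p of 0.283 with an estimated correlation. Of these, 5 passed adjusted over the list alone and 0 over all genes. Beta-globin (the joined row Hbb-b1 and Hbb-bs) was at 104 ± 52.6 and 24.4 ± 18.4 FPKM, and the medians of the list were -1.49, -0.02 and -1.53 within pairs A, B and C. Without pair B this joined row (log2 fold change -3.17, limma adjusted p = 0.0151) and Hbb-bt (-3.00, 0.0338) passed over all genes. The 14 mesenchymal markers had a median of -0.64 (adjusted p = 0.00117, 0.926 with an estimated correlation, 0.0774 without mutant A), and 0 passed over all genes or the list alone, with 1 under the block. These markers were lower in control A, mutant A and mutant C than in the other libraries, by a median difference of -1.31 (log2), and with their mean level as a covariate 7 of the 16 genes remained called. The 9 that lost the call kept log2 fold changes of 0.90 to 1.05 times the size, with an SE of 0.83 to 1.11 times and adjusted p up to 0.103. Pdgfrb, a receptor of pericytes, was at 24.2 ± 10.6 and 9.95 ± 5.07 FPKM. The 6 mesothelial markers had a median of -0.30 (adjusted p = 0.496, 0.0175 with the block, 0.0357 without mutant B, 0.926 with an estimated correlation and 0.657 with the block and an estimated correlation), with 1 lower under the block.

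Some epithelial markers were lower in the mutant and others were not. The 8 alveolar type 1 markers had a median of -0.44 (adjusted p = 0.00178, 0.283 with an estimated correlation), with 0 passing over all genes and 3 adjusted over the list alone. These were Hopx, at 59.5 ± 1.42 and 14.8 ± 8.07 FPKM (-2.10 ± 0.41, adjusted p = 0.262; 0.0245 without mutant C), Gprc5a and Spock2. Vegfa is also on that list. Ager, the receptor most typical of these cells, was at 12.5 ± 3.08 and 11.5 ± 2.14 FPKM (-0.10 ± 0.20). The 7 alveolar type 2 and airway markers had a median of -0.55 (adjusted p = 0.0479, 0.926 with an estimated correlation), and 0 passed over all genes or the list alone, with 1 under the block. That call ended without control A (0.238), control B (0.489), mutant B (0.225) or mutant C (0.289), and with median-of-ratios rescaling (0.0593). Sftpc, the surfactant protein of type 2 cells, was at 83.6 ± 55 and 29.5 ± 17.1 FPKM (adjusted p = 0.617).

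The authors' deposited table gave a log2 fold change and a p-value for 14338 rows, and a spreadsheet error in the other 9455, which include Snora17. A p under 0.05 was given for 1079 rows of the authors' deposited table, of which 553 were lower and 526 higher in the mutant. By chance alone a share of about 0.05 of the 14338 rows would fall under that threshold. In the authors' deposited table the log2 fold change was -2.81 for Sirpa (p = 0.000884), -3.71 for Chst1 (p = 0.00339), -4.74 for Car4 (p = 0.0493), -2.38 for Ednrb (p = 0.0211) and -0.29 for Kdr (p = 0.116). These p-values were not adjusted: after Benjamini-Hochberg adjustment of those in the authors' deposited table, 0 rows were under 0.05 and the smallest value was 0.0625. A paired test over 3 pairs has few degrees of freedom and can hardly pass this adjustment, so this does not show that no gene differed.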

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

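The settings without short RNA rows, without pair B or pair C, with the mesenchymal covariate, and with the block and an estimated correlation together were chosen after seeing the data. The 16 lower genes became 10 with a mean of at least 5 FPKM, 6 with the replicate block, 7 with the mesenchymal covariate, 5 with only the libraries prefixed Vegfa2, 8 without pair B, 2 without pair C and 31 with array weights, and 5 to 8 without any single library. All 6 genes of the block fit, all 7 of the covariate fit and 4 of the 5 in the Vegfa2 libraries were among the 16, and array weights kept all 16. The other settings gave 11 to 16 genes. The count of 0 higher genes became 1 in the Vegfa2 libraries, 1 without pair C, 2 with array weights and 0 to 2 without any single library; apart from BC064078 and a joined row of C430049B03Rik with 3 microRNAs under array weights, these were microRNAs or small nucleolar RNAs. The cause of these changes was not tested, except that fewer libraries leave fewer degrees of freedom.

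Of the 9 lists called, 0 held with an estimated correlation, 0 with the block and an estimated correlation, and fry, which tests a list against no change and not against the other genes, called 2 of them (Car4-high capillary markers and p53 targets). The calls lost with an estimated correlation do not rest on gene correlation alone. The p53 targets had an estimated correlation of -0.048, below the preset 0.01, and still went from an adjusted p of 0.00507 to 0.283 in camera. That test rests on the 4 residual degrees of freedom of the fit, and on fewer with the block, so it cannot show that a list did not change. Without any single library 7 to 9 of these 9 were kept, and 8 to 14 lists were called in all. The Car4-high capillary list was called in 15 of its 17 alternatives, with adjusted p from 4.41e-20 to 0.657. The list of lymphatic markers turned, from a mean of 0.20 to -0.23 (adjusted p = 0.0382) with the mesenchymal covariate; the cause was not tested. With that covariate the pan-endothelial (0.0319), growth factor early response (1.84e-05), basement membrane (0.0382) and leukocyte (0.0221) lists also gained a call, and the mesenchymal list, which the covariate removes, lost it. Without pair B the p53 (0.0789) and alveolar type 2 and airway (0.719) lists lost their calls, and without pair C the mesenchymal list did (0.0666). Calls were gained without pair B by the dissociation stress (0.000306) and mesothelial (0.0268) lists, and without pair C by the interferon (0.00363), MHC class II (0.00258), basement membrane (0.0426) and leukocyte (0.00403) lists. Apart from the values with the block given in the report, the block changed no other call of a list. Over 24 settings the 16 genes kept their call 228 times and lost it 151 times, with no change of direction. Sirpa kept it in 24 of 24 and Krt80 in 23 of 24 alternatives. Among uncalled named genes 6 calls were gained and the sign changed 46 times without a call. The depth is known only relative to control A, so no limit of detection could be given.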

Other observations

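The genes in this paragraph and the next were chosen after their values were seen, and so were the tests on alveolar type 1 markers, on the cell cycle genes within pairs, on the markers of other endothelial types against the cell cycle genes, and on the mesenchymal markers. The criteria of these tests were also changed after results were seen, and earlier ones left the mesenchymal cells of the first pattern and the other endothelial types open. The third pattern replaced another one, inflammation genes highest in mutant C, after the splits were seen, and the causes of that one are not weighed here. H19, a long non-coding RNA of an imprinted locus, was at 36.8, 37.8 and 57.6 FPKM in controls A, B and C and at 99.3, 201 and 137 FPKM in mutants A, B and C (log2 fold change 1.67 ± 0.28, limma adjusted p = 0.211). BC064078 had the lowest adjusted p among the genes with a higher mean, 0.101, at 1.4 ± 0.365 and 4.77 ± 0.825 FPKM. The groups did not overlap in 833 genes that were higher and 768 that were lower in the mutant, together 13.7% of those tested, where chance gives 10% if the 6 libraries are exchangeable. The letters pair the libraries, and the 3 other splits that part all pairs gave 3.69% to 7.06%.

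Mutant C stood apart from mutants A and B in several genes. Fabp4, a fatty acid binding protein, was at 218 FPKM in mutant C and at 33.8 and 23.3 FPKM in mutants A and B, and Fabp5 at 156 FPKM against 23.7 and 22 FPKM. Oit3 was at 21.9 FPKM against 1.68 and 0.912 FPKM, and the adhesion molecule Selp at 19.4 FPKM against 4.08 and 1.15 FPKM. Slc6a2 was at 0.506 FPKM in mutant C and at 14.8 and 21 FPKM in mutants A and B, and Prx at 34.4 FPKM against 149 and 152 FPKM. Nxpe4 was at 0.479 and 0.45 FPKM in mutants B and C and between 14.6 and 18.7 FPKM in the other libraries, and Hapln3 was at 0.478 FPKM in mutant A and between 5.11 and 7.21 FPKM in the others.

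The first pattern weighed is the fall of the 15 called genes other than Snora17. Fewer alveolar type 1 cells in the mutant sorts cannot be told apart from a change of the endothelium: the 4 fixed markers other than Vegfa with at least 5 FPKM in control had a median of -0.78 with an interval over genes from -2.10 (Hopx) to -0.10 (Ager), against -1.76 for the called genes, while all 7 markers other than Vegfa, several near the floor, had -0.62 (-0.93 to -0.10). Between mutant A, with most of these markers, and control C, with least, the 4 differed by -0.14 (-1.72 to 0.52) and the 7 by -0.29 (-0.67 to 0.32). The called genes differed by -1.73 there, but these are single libraries and both intervals hold 0. The list with Vegfa had medians of 0.08, -0.70 and -0.49 within pairs A, B and C, against -1.76, -1.75 and -1.80 for the called genes. In pair A the markers as a set thus did not fall, though Hopx did (-1.76). Fewer mesenchymal cells are argued against as the source of the whole fall, by the levels of their markers only. Their markers fell in every pair, by -0.60 (interval over genes -0.78 to -0.29) in A, -0.12 (-0.43 to -0.0014) in B and -1.15 (-1.87 to -0.97) in C. The called genes fell by -1.76, -1.75 and -1.80. Across pairs, mutant B had more of the markers than control A (median difference 0.99, interval over genes from 0.68 to 1.42) while the called genes differed by -1.61. The direction of the called genes there was fixed by their selection, since each has all mutant libraries below all controls, and the comparison is of single libraries. The even fall of the called genes over the pairs was also favoured by selection, as a small spread helps a gene to be called. The mesenchymal markers were not selected in this way. They vary together (estimated correlation 0.91), so their intervals over genes are too narrow. Variants carried along with engineered loci are argued against too, as 0 of the called genes lie within 10000000 bases of Vegfa or Shh. The real grouping gave 16 genes and the highest of the other 9 splits of the 6 libraries gave 147 (2 of 10 splits gave at least 16), and 10 splits are too few for a share under 0.05; among the 4 splits that part all pairs the highest other count was 0. A change in the share of Car4-high capillary cells and a lower expression within each cell stay open beside these.

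The second pattern is the higher level of cell cycle genes. Their median difference was 1.24 in pair B, 0.39 in pair C and 0.059 in pair A, so whether pair B alone could account for it cannot be told apart from a difference of the groups with 3 pairs; without pair B the median was 0.25 in place of 0.59, which an earlier criterion took as arguing against pair B, and the criterion was made stricter after that result was seen. A larger share of the other endothelial types after a loss of 1 capillary type would raise their markers as much as the cell cycle genes. The values within pairs B and C argue against it for those pairs. In pair B the cell cycle genes had a median of 1.24 (interval over genes 1.14 to 1.32) and the other markers 0.017 (-0.074 to 0.074). In pair C these were 0.39 (0.31 to 0.49) and 0.097 (-0.021 to 0.26). The 38 general capillary, arterial, venous and lymphatic markers had a median of 0.089 (95% interval over genes 0.0063 to 0.17, within pair B 0.017 and within pair C 0.097). This lay below the lower bound of 0.51 for the cell cycle genes. Both intervals are over genes of the same libraries, and the cell cycle genes vary together, with estimated correlations of 0.83 for the S phase list and 0.85 for the G2 and M list. The cell cycle median exceeded that of the other markers by 1.23 in pair B and 0.29 in pair C, and by -0.01 in pair A. Over the pairs, of which A shows no difference to explain, the excess of the cell cycle genes was 0.50 with an interval from -1.10 to 2.11. The argument is therefore limited to pairs B and C. For all lists together, the real grouping called 9 and the highest of the other splits called 13, with 5 of the 10 splits calling at least 9, too few splits for a share under 0.05, and the other splits each called at least 6; among the 4 splits that part all pairs the highest other count was 9, as many as the real one. More division in the mutant endothelium stays open and untested.

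The third pattern came from those splits. The split with 147 calls set control A, mutant A and mutant C against the rest, several times the count of the mutant and control comparison, and points to a structure of the libraries: 141 of these genes were lower in those 3 libraries, 5 were mesenchymal markers of the fixed list and 0 were among the 16. The 14 mesenchymal markers, among them Col1a1, Col3a1 and Pdgfra, had a median difference of -1.31 (95% interval over genes from -1.48 to -1.25), but they are part of the pattern, so fewer mesenchymal cells in these libraries cannot be told apart from lower expression of these genes. Uneven scaling of the libraries would have lowered endothelial genes too, but the pan-endothelial genes differed by 0.15 (0.025 to 0.29). The libraries came from both groups, and no biological explanation was tested.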
